A study of Arabidopsis thaliana with 12 samples.

How the data were processed

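RNA from whole roots of the 12 samples was hybridised to Affymetrix arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled sense-strand DNA targets were prepared from it. Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.3. The summarization and normalization methods are not given in the sources used here. The deposited values were taken as log2 expression, because they ran from 0.426 to 13.98, which exceeds the natural log of the largest 16-bit scanner reading. They were used as deposited and were not normalized again. The table held 38408 rows, and array medians over all rows were 6.07 to 6.14 without CHX and 5.62 to 5.68 with CHX, while over the genes tested they were 5.87 to 5.92 and 5.98 to 6.03. No detection call or background level was used here, so low values have no stated floor.

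Rows were named through the array's platform annotation. Of the 38408 rows, 16722 were paired with 1 gene, 759 with several and 20927 were unnamed there, which does not mean that they match no gene. The 16722 rows gave 16550 genes, each read from the probe set with the highest mean over all arrays, so 172 further probe sets were left out. Gene symbols came from the RefSeq table of assembly TAIR10.1 through the gene identifier, which matched 16411 genes and left 139 with the annotation's own name. The coverage was uneven. Among the names given there 85.8% of the protein-coding genes known by locus alone were measured, against 16.8% of those with another symbol, so 14745 of the tested genes are named by locus and 1805 by symbol. No coordinates are given, because the build behind the array annotation is not stated in the sources used here.

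The analysis used R 4.3.3 and limma 3.58.1. A linear model with 1 mean per treatment was fitted to all 12 arrays, so that the 4 treatments shared an estimate of the spread, and moderated tests from eBayes were two-sided. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over 16550 genes, with no fold minimum. The contrasts were DEX against mock, DEX with CHX against CHX, CHX against mock, and the difference of the first 2. A fold change is the antilog of a difference of mean log2 values, and ± after it is the standard error of the fit. The method was tested on simulated arrays of 16550 genes with 200 changed. For DEX against mock it recovered 38.8% of the genes changed by 0.5, 82.1% of those changed by 1 and 100% of those changed by 2 on the log2 scale. For DEX with CHX against CHX the shares were 28.4%, 80.6% and 97%. Of the calls, 8.12% and 4.2% were false, and an unchanged comparison gave 0. The first share is above the threshold of 0.05. Noise was drawn independently for each gene and array, with 1 simulated set per comparison. Real arrays can share deviations across genes and arrays, so these rates need not hold for them.

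Before the data were examined, 18 gene lists with 324 loci were fixed for lateral roots, auxin, the cell cycle, cell walls, stress and markers of other root or shoot cells. Of the loci, 53 were measured. The 6 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. No member of the lists for root stem cells, very-long-chain fatty acids, xylem or phloem was measured, and the other lists had 1 or 2. MCM7, listed as PRL, and ARR15 were measured and not called in any contrast, except that ARR15 was called for CHX against mock with just the arrays compared (0.45, adjusted p = 0.0353). LBD16 was compared by exact permutation.

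Genes are named by a rule fixed with the lists. It takes the 10 genes higher and 10 lower with the largest fold change in each DEX comparison, and 5 each for CHX, among called genes whose arrays did not overlap between the groups. It adds the 5 positive and 5 negative interactions with the largest difference, the 10 genes per direction with the largest change common to both DEX comparisons, up to 4 members with the smallest p per list and contrast, and allows any lateral root regulator to be named. Members of other lists with no call are named as examples chosen after their values were seen.

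The replicate numbers in the labels were checked for pairing by the correlation, across genes, of deviations from the group mean. For CHX and DEX with CHX these were 0.244, 0.157 and 0.332 for replicates 1, 2 and 3. Same-numbered arrays were read as pairs there, which rests on the data. The main tests did not pair arrays, and the replicate number entered as a block in an alternative fit. No 2 arrays held identical values. The alternatives were the replicate number as a block, quantile normalization, centring each array, leaving out the dimmest 30% of genes, testing all rows, averaging a gene's probe sets, a trended and robust variance, a fit to just the arrays compared, a fold minimum of 2, an adjusted p of 0.01, fry in place of camera, and leaving out each array. Leaving out replicate 3 of all treatments, reading the DEX change from arrays not used to pick the genes, and a screen of gene families by symbol were added after the data were seen. The result of 1 screened family is not reported here.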

Results

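Gene expression was measured in roots of Arabidopsis thaliana seedlings that carried LBD16 fused to the hormone-binding part of the glucocorticoid receptor (GR). LBD16 is a transcription factor of the LATERAL ORGAN BOUNDARIES DOMAIN family that acts in lateral root initiation. The fusion was driven by the strong 35S promoter in a mutant that lacks ARF7 and ARF19, the auxin response factors that normally switch on LBD16 in roots. The synthetic steroid dexamethasone (DEX) lets a GR fusion enter the nucleus, and cycloheximide (CHX) blocks protein synthesis. Seedlings 5 days old were treated for 4 hours with mock solution, 2 µM DEX, 10 µM CHX, or both, and each of the 4 treatments was measured on 3 arrays. Per the labels, the arrays of a treatment were 3 independent sets of RNA. All 12 arrays came from this 1 line, so no array shows what DEX does in roots without the fusion. The number of arrays limits the precision. Replicates of a treatment correlated at 0.992 to 0.994 across genes, against 0.873 to 0.885 between arrays with and without CHX.

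LBD16 itself was read at a high and even level in every array, with values from 9.29 to 9.67 on the log2 scale. The group means were 9.49 ± 0.06 (SD, n = 3) with mock, 9.33 ± 0.05 with DEX, 9.60 ± 0.08 with CHX and 9.52 ± 0.07 with both. These probes can read the transgene and the native gene, so the level shows that the line expressed LBD16 and says nothing of where the fusion protein was. With DEX it differed by -0.17 on the log2 scale without CHX (exact two-sided permutation test, p = 0.1, the smallest p that 3 arrays against 3 allow) and by -0.09 with CHX (p = 0.3). With CHX it differed from mock by 0.11 (exact permutation test, p = 0.2).

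The comparison of DEX with mock asked which transcripts change when the fusion is activated while proteins can still be made. The strongest rises were those of AT1G07690, which was 11.4-fold higher with DEX (log2 fold change 3.51 ± 0.15 SE, n = 3 per group, limma adjusted p = 2.45e-07), and AT1G62770, a member of the pectin methylesterase inhibitor family, which was 10.7-fold higher (3.42 ± 0.13, adjusted p = 1.64e-07). AT1G07690 rose from 5.65 ± 0.20 (SD) to 9.16 ± 0.19, and AT1G62770 from 5.11 ± 0.08 to 8.53 ± 0.20. GH3.5, also called WES1, which encodes an enzyme that joins auxin to amino acids, rose 5.58-fold (2.48 ± 0.10 SE, adjusted p = 2.45e-07). AT3G22060, a cysteine-rich secreted protein related to receptor kinases, rose 7.17-fold, and AT5G65320, a bHLH transcription factor, rose 7.19-fold. AT4G37295 rose 9.75-fold, AT5G55800 7.16-fold, AT1G64405 6.55-fold, AT3G57950 6.55-fold and AT2G43470 6.16-fold. The falls were smaller. AT2G25150, an acyltransferase of the HXXXD type, fell by 1.72 on the log2 scale (SE 0.21, adjusted p = 0.00112), and AT5G22860, a serine carboxypeptidase of the S28 family, fell by 1.65 (SE 0.17, adjusted p = 0.000239). GH9B17, an endoglucanase, fell by 1.22, TINY, a transcription factor of the DREB group, fell by 1.11, and AT5G39080, another acyltransferase, fell by 1.11. AT1G58320 fell by 1.35, AT2G18490 by 1.31 and AT4G00910 by 1.07.

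In all, 252 of 16550 genes passed an adjusted p of 0.05 with DEX, 184 of them higher and 68 lower. Among these, 75 of the higher and 10 of the lower genes changed by at least 2-fold. The lower list also held BGLU45, a beta-glucosidase, at -1.27 (adjusted p = 0.0216), and AT3G20850 at -1.09 (adjusted p = 0.0271). Both were borderline, because leaving out any of 4 arrays ended the call of BGLU45 (adjusted p from 0.0613 to 0.0905) and leaving out any of 5 ended that of AT3G20850 (0.0599 to 0.101). Both also missed it with all rows tested (0.0507 and 0.0615) and with just the arrays compared (0.063 and 0.068). AT2G18490 missed the threshold when the fit held just the arrays compared (adjusted p = 0.0603). Without replicate 3 of every treatment so did AT1G58320 (adjusted p = 0.0821), AT5G39080 (0.212), AT4G00910 (0.0933), AT2G18490 (0.235), BGLU45 (0.223) and AT3G20850 (0.0811). The 68 lower genes came to 41 without DEX replicate 1, 41 without mock replicate 2, 44 without DEX replicate 2, 29 without mock replicate 3 and 32 without DEX replicate 3. The 184 higher genes came to 121 without mock replicate 3. The count of 252 fell to 150 without mock replicate 3, to 62 without replicate 3 of all 4 treatments, which was left out after the data were seen, and to 130 when the fit held just the mock and DEX arrays. A fold minimum of 2 left 85 genes and an adjusted p of 0.01 left 120.

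**Figure D1:**
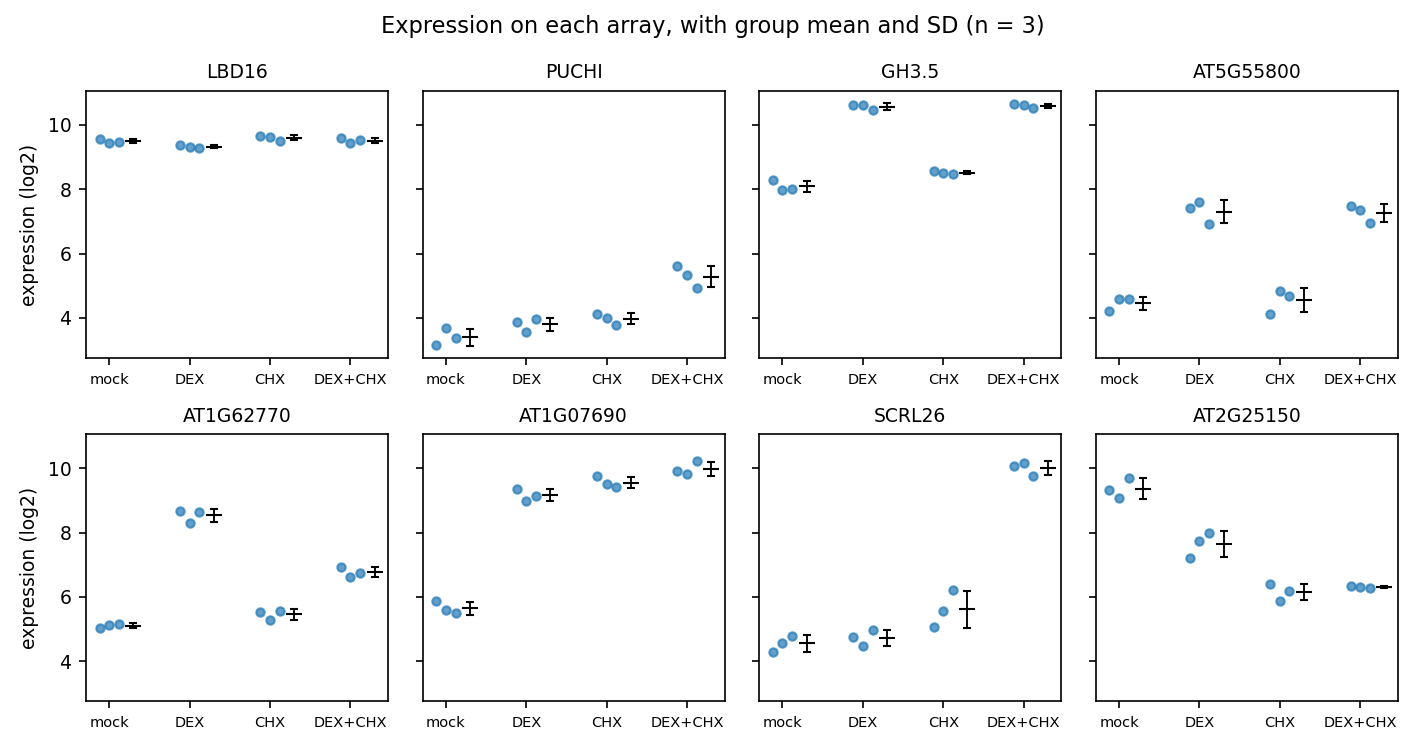
Expression of 8 genes on each of the 12 arrays, in log2 units (vertical axis, the same in every panel) by treatment (horizontal axis). Points are arrays, and the bar beside them is the mean with its SD (n = 3). LBD16 lies between 9.29 and 9.67 throughout, GH3.5 and AT5G55800 are higher with DEX both without and with CHX, and SCRL26 is at 4.73 with DEX and at 10.00 with DEX and CHX together.

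Of the gene groups tested, the GH3 family passed with DEX through 2 of its genes, while its median log2 change was 0.0683. Of its 6 measured members, 2 rose, both over all genes and adjusted over the list alone, and none fell. These were GH3.5 and GH3.1 (log2 fold change 1.11 ± 0.16, adjusted p = 0.00309), another auxin-conjugating enzyme, whose call was lost with just the arrays compared (adjusted p = 0.0564) and without replicate 3 of every treatment (0.107). GH3.3 stood at 0.01, GH3.9 at -0.05 and GH3.17 at 0.13, none of them past the threshold. The family ranked above other genes by camera (adjusted p = 0.00319, and adjusted p = 0.0451 with an estimated correlation). Of 29 listed Aux/IAA genes, a family of auxin-response repressors, 8 were measured. None of the 8 passed the threshold (camera adjusted p = 0.834), IAA18 being at 0.44 and IAA30 at 0.51. None of the 3 measured LBD genes did so either (0.441), with LBD29 at -0.02. Among the 6 measured lateral root regulators none was called (0.834). PUCHI, an AP2-type factor needed for the shape of lateral root primordia, was at 0.40 (adjusted p = 0.498) and ACR4 at -0.19 (adjusted p = 0.723). The mock and DEX means of PUCHI both lay in the range of the dimmest 30% of genes (up to 4.15). Low values have no stated floor, so its missing call does not show a lack of response. Of 17 expansins, which loosen cell walls, EXPA20 rose (0.57 ± 0.12, adjusted p = 0.0343). Adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.917). The EXPA20 call ended when any of 7 arrays was left out (adjusted p from 0.0529 to 0.13), with the mean of its probe sets (0.126), with all rows tested (0.0638) and with just the arrays compared (0.134). None of the 4 auxin synthesis genes measured was called (0.713). Markers of other tissues were few. The shoot genes RCA and PORB stood at -0.41 and -0.60 with DEX and were called lower adjusted over the list alone, not over all genes (adjusted p = 0.45 and 0.42). The root hair expansin EXPA7 stood at 0.41 (adjusted p = 0.0996) and was called higher over its list alone, with the replicate number as a block (0.0447) and with a trended, robust variance (0.0434).

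The comparison of DEX with CHX against CHX alone asked which transcripts change when the fusion is activated while protein synthesis is blocked. SCRL26, a small cysteine-rich secreted peptide, was 20.9-fold higher (log2 fold change 4.39 ± 0.25 SE, n = 3 per group, adjusted p = 3.37e-06), going from 5.62 ± 0.57 (SD) to 10.00 ± 0.21. AT2G12462 was 17.1-fold higher (4.09 ± 0.19, adjusted p = 1.84e-06). AT1G64405 rose 8.60-fold, AT4G03420 7.55-fold, AT5G55800 6.51-fold, AT3G57960 5.94-fold, AT3G16660 5.78-fold and AT1G03820 4.88-fold. AT5G65320, the bHLH gene, rose 4.46-fold, and GH3.5 rose 4.25-fold (2.09 ± 0.10, adjusted p = 1.84e-06). In all, 98 genes were called, 91 higher and 7 lower, and 50 of the higher genes and 1 of the lower changed by at least 2-fold. AT1G12665 fell by 1.24 (SE 0.18, adjusted p = 0.00785) and AT4G28420, which resembles tyrosine aminotransferases, fell by 0.88 (SE 0.12, adjusted p = 0.00329).

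The other 5 lower genes were weaker calls. AT5G10410 stood at -0.80 (adjusted p = 0.0123), the carboxylesterase gene AT5G06570 at -0.60 (0.0459), the subtilase gene AT5G45650 at -0.58 (0.0343), AT3G54410 at -0.54 (0.0425) and AT5G24320 at -0.52 (0.0353). Same-numbered arrays of these groups deviated together, and with the replicate number as a block AT5G06570, AT5G45650 and AT3G54410 missed the threshold (adjusted p = 0.075, 0.0543 and 0.0634). Each of the 5 missed it when 1 of at least 3 single arrays was left out, with adjusted p up to 0.0682 for AT5G10410, 0.177 for AT5G06570, 0.171 for AT5G45650, 0.201 for AT3G54410 and 0.174 for AT5G24320. With just the arrays compared they stood at 0.0568, 0.185, 0.141, 0.124 and 0.155. Without replicate 3 of every treatment all 7 lower genes missed it, AT1G12665 at 0.287 and AT4G28420 at 0.205. The 7 lower genes came to 3 without DEX+CHX replicate 1, 3 without CHX replicate 2, 2 without DEX+CHX replicate 2 and 3 without DEX+CHX replicate 3. The count of 98 was 62 without DEX+CHX replicate 1, 64 without DEX+CHX replicate 2, 64 without CHX replicate 3, 27 without replicate 3 of every treatment and 61 with just the arrays compared. A fold minimum of 2 left 51 genes and an adjusted p of 0.01 left 55.

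In the gene groups, the GH3 family again ranked above other genes under CHX (camera adjusted p = 1.51e-06, and adjusted p = 0.00444 with an estimated correlation). GH3.5 was called over all genes, and 3 of the 6 members were called higher adjusted over the list alone. GH3.3 stood at 0.92 (adjusted p = 0.228) and was called with the replicate number as a block (0.0445). GH3.1 stood at 0.58 (adjusted p = 0.278) and was called without DEX replicate 2 (0.0486). PUCHI rose 1.31 ± 0.19 on the log2 scale (adjusted p = 0.00614), from 3.98 ± 0.17 (SD) to 5.29 ± 0.34, and was the called gene among the 6 lateral root regulators, over all genes and over the list alone. Without replicate 3 of every treatment PUCHI stood at 1.40 (adjusted p = 0.0904). LBD29 was at 0.09, RALFL34 at 0.20, ACR4 at -0.15, CEP5 at 0.19 and LHW at -0.04, none of them called. The list as a whole did not pass the test (camera adjusted p = 0.0844, and 0.164 with an estimated correlation). It passed without CHX replicate 1 (0.029) and without DEX+CHX replicate 2 (0.0192). EXPA20 rose 0.66 ± 0.12 (adjusted p = 0.0239), 1 of 17 expansins (camera adjusted p = 0.998), and its call ended without any of 5 arrays (adjusted p from 0.0535 to 0.134), with all rows tested (0.0522), with the mean of its probe sets (0.213) and with just the arrays compared (0.101). Of 8 Aux/IAA genes none was called over all genes and 1 was called higher adjusted over the list alone (camera adjusted p = 0.72). The LBD (0.757) and auxin synthesis (0.72) lists held no called gene. RCA stood at 0.00 and PORB at 0.03. ARR16, listed as RR16, a cytokinin response regulator, stood at 1.01 (adjusted p = 0.07) and was called higher over its list alone, without the dimmest genes (0.0442), with a trended, robust variance (0.0316) and without DEX replicate 1 (0.0456).

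The calls of the 2 DEX comparisons were then set side by side. The comparisons contrast different arrays, but the fit gave both the same estimate of each gene's spread, so their calls are not independent. Of the genes called higher, 47 were called higher in both, against 1.01 expected for independent lists (two-sided Fisher's exact test, p = 3.39e-69). That test takes the lists and the genes as independent, which they are not, so its p is descriptive. AT1G64405 had the largest rise common to both, at least 6.55-fold in each. AT5G55800, AT5G65320, GH3.5, AT3G57960, AT3G57950 and AT2G12462 also rose in both. AT2G43220 rose by log2 1.60 and 1.84 without and with CHX, AT2G33350 by 1.53 and 1.94, and AT1G77280 by 1.51 and 2.02. AT5G06570 was the 1 gene called lower in both, at -0.92 (adjusted p = 0.00148) and -0.60, and no gene was called in opposite directions. Without replicate 3 of every treatment AT5G06570 (adjusted p = 0.0818) and AT2G12462 (0.0509) missed the threshold for DEX against mock. A further 137 genes were called higher and 67 lower without CHX alone, and 44 higher and 6 lower with CHX alone. Of the 184 genes higher without CHX, 152 had a positive change with CHX, with a median log2 fold change of 0.876 without and 0.331 with CHX. Of the 91 genes higher with CHX, 85 had a positive change without it, with medians of 1.04 with and 0.669 without CHX. Each set was picked on the arrays that show its larger median. Of the 68 lower genes, 48 had a negative change with CHX, with medians of -0.732 and -0.0892. Across all genes, which are not independent replicates, the 2 effects correlated at r = 0.277 (Spearman's rho 0.136). The 48 genes called in both came to 31 without DEX+CHX replicate 1 or without CHX replicate 3. Leaving out replicate 3 of every treatment gave 14. With just the arrays compared, where the 2 fits shared no array, 23 genes were called in both. A fold minimum left 20 and an adjusted p of 0.01 left 26.

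**Figure D2:**
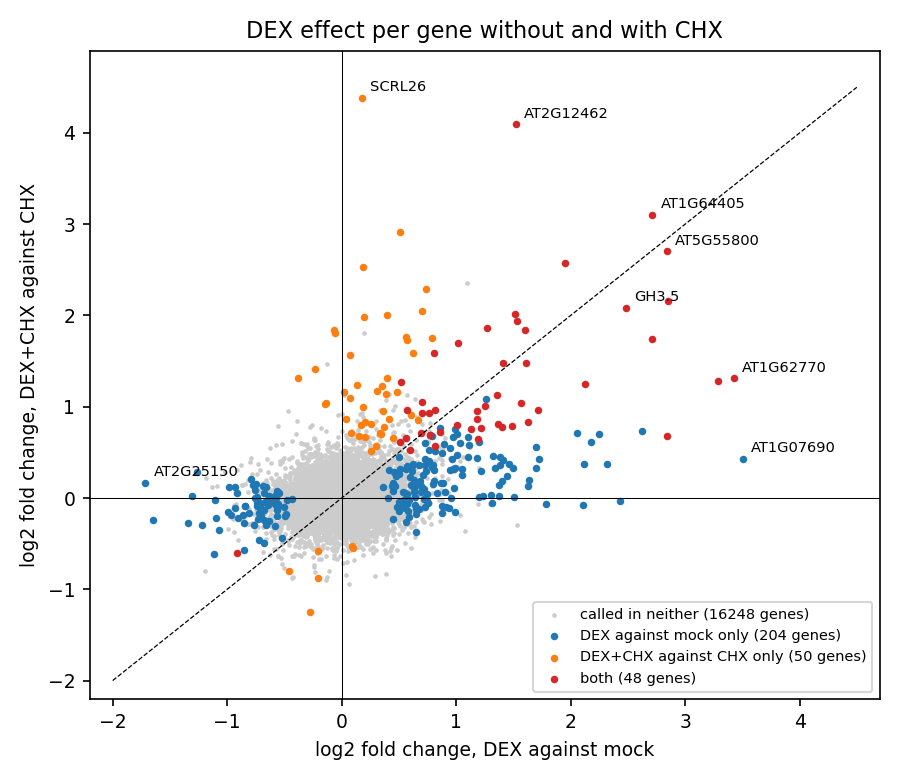
Each point is 1 of 16550 genes, with its log2 fold change for DEX against mock on the horizontal axis and for DEX with CHX against CHX on the vertical axis. Colours mark genes called in both comparisons (48), in DEX against mock only (204), with CHX only (50) or in neither, and the dashed line marks equal effects. Most points called in both lie in the upper right, AT1G07690 lies near the horizontal axis at 3.51, and AT2G12462 lies above the dashed line.

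The interaction tested whether the DEX effect itself differed with CHX present. It was called for 21 genes, 7 with a positive difference and 14 with a negative. Of the 7, 6 were called higher with DEX under CHX, and all 14 were called higher with DEX alone. The largest positive difference was that of SCRL26, at 4.21 ± 0.36 SE on the log2 scale (adjusted p = 0.000403), since it stood at 4.55 with mock and 4.73 with DEX alone. AT2G12462 differed by 2.57 (adjusted p = 0.00214). It rose 2.87-fold with DEX from a high mock level of 10.27, and 17.1-fold under CHX, where the level without DEX was 5.13. AT4G03420 differed by 2.41 and AT3G16660 by 2.34. AT2G25150 differed by 1.88 (adjusted p = 0.0373), having fallen with DEX alone while its change with DEX was 0.17 under CHX. CHX alone had lowered it from 9.36 with mock to 6.15, below its level of 7.65 with DEX alone. Its interaction was lost with any of 9 arrays left out (adjusted p up to 0.106), with the replicate number as a block (0.0599) and with all rows tested (0.103). On the negative side, AT1G07690 differed by -3.07 ± 0.21 (adjusted p = 0.000179). CHX alone brought it to 9.55, above its level of 9.16 with DEX alone. AT3G22060 (-2.16) was also raised by CHX, to 10.24, below its level of 10.71 with DEX alone. AT1G10640, which encodes a pectin-degrading enzyme of the polygalacturonase type, differed by -2.46. It rose from 5.33 to 7.76 with DEX alone and stood at 5.18 with CHX and 5.16 with both. AT2G19970, of the pathogenesis-related-1-like family, differed by -2.18, and AT1G62770 by -2.11. For PUCHI the difference was 0.91 (adjusted p = 0.384), so over all genes its rise under CHX was not shown to differ from its change without CHX, while adjusted over the list alone 1 of the 6 lateral root regulators was called with a positive difference. Adjusted so, 1 of the 17 expansins and 1 of the 2 root hair markers were called with a negative difference, EXPA7 standing at -0.67. No listed gene group passed camera for the interaction, the lateral root list (adjusted p = 0.134) passing without DEX+CHX replicate 2 (0.0451). The count of 21 was 2 without replicate 3 of every treatment, where of the genes named here just SCRL26 and AT1G07690 were called, 32 with all rows tested and 53 with a trended, robust variance.

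CHX against mock gave the effect of the inhibitor alone, the background for the DEX comparison under CHX. It changed 9088 of 16550 genes (54.9%), 4002 higher and 5086 lower, and 2081 of the higher and 1752 of the lower genes changed by at least 2-fold. The beta-glucosidase gene BGLU27 was 391.7-fold higher (log2 fold change 8.61 ± 0.10 SE, adjusted p = 2.15e-13), from 3.03 ± 0.12 (SD) to 11.64 ± 0.04. The transcription factor gene WRKY41 was 352.4-fold higher and BGLU32, another beta-glucosidase, 325.7-fold. AT2G04070, of the MATE transporter family, rose 342.7-fold and AT1G05675, a glycosyltransferase gene, 325.1-fold. BGLU27 began in the range of the dimmest 30% of genes (up to 4.15). Low values have no stated floor, so the size of a fold that begins there is uncertain. AT4G03292 fell by 5.90 on the log2 scale, AT3G49330 by 5.85, AT4G30450 by 5.49, AT2G12462 by 5.13 and AT1G28815 by 4.92. Centring each array on its median lowered the median change of all genes by a further 0.118, from -0.0766 to -0.195, with 3468 genes called higher and 6081 lower, and quantile normalization gave 3586 and 5809. The share of higher genes thus went from 44% to 36.3% and 38.2%, so the balance of the directions depends on the scaling. Testing all rows of the table called 23040 of them, 6998 higher and 16042 lower (30.4% higher), and a fold minimum of 2 left 3833 genes.

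Among the gene groups under CHX, the zinc finger gene ZAT10, listed as STZ, an early stress-response factor, rose by log2 6.13 ± 0.20 (adjusted p = 1.93e-10), and GSTU25, a glutathione transferase of detoxification, by 2.81 ± 0.14. Of 8 Aux/IAA genes 3 rose and 2 fell, also adjusted over the list alone, with IAA30 at 3.36 ± 0.22 and IAA33 at -1.51 ± 0.19 (camera adjusted p = 0.699). In the GH3 family 3 rose and 1 fell, led by GH3.1 at 4.38 ± 0.16, while GH3.17 was at -1.05 ± 0.10 (0.574). Of 17 expansins 7 rose and 4 fell, with EXLA3 at 6.23 ± 0.21, EXLA2 at 3.05 ± 0.22 and EXPB3 at -2.18 ± 0.21 (0.574). With either other scaling 6 rose and 5 fell. Among the 6 lateral root regulators RALFL34, which encodes a signalling peptide, fell by 2.00 and LHW, a bHLH factor of vascular development, fell by 0.81 (0.602). Over this list 2 genes were called higher and 2 lower, also adjusted over the list alone, against 2 higher and 4 lower with quantile normalization and 1 higher and 3 lower with centring. ACR4, listed as CR4, a receptor kinase gene, stood at -0.17 (adjusted p = 0.288). The signalling peptide gene CEP5, listed as AT5G66815, stood at 0.92 and PUCHI at 0.58, both called. Those calls were fragile, ending without CHX replicate 1 or without mock replicate 3 for both, also without mock replicate 2 for CEP5 (adjusted p from 0.0721 to 0.117) and without mock replicate 1 or CHX replicate 2 for PUCHI (0.0516 to 0.0848). Centring the arrays ended the call of PUCHI too (adjusted p = 0.0597). Of the 4 auxin synthesis genes measured 3 fell, YUC2 by 1.03, YUC6 by 1.02 and YUC11 by 0.29 (0.574). The call of YUC11 (adjusted p = 0.044) ended when any of 7 arrays was left out (0.0505 to 0.139), with the block (0.0587), with quantile normalization (0.069) and with a trended, robust variance (0.133). No LBD gene was called (0.921), but LBD29, at -0.39 (adjusted p = 0.13), was called lower with quantile normalization (-0.56, adjusted p = 0.0268), with centring (-0.51, 0.0464) and without mock replicate 3 (-0.61, 0.0194). The mitotic kinase genes AUR1 and AUR2 fell by 0.60 and 1.06, and the cytokinin response regulator ARR16, listed as RR16, fell by 1.78. The receptor kinase gene SGN3, listed as GSO1, rose 0.42, a call lost without replicate 3 of every treatment (adjusted p = 0.0587). The root hair expansins EXPA7 and EXPA18 fell by 0.40 and 1.05, and of the shoot genes RCA fell by 0.87 while PORB stood at 0.59 (adjusted p = 0.0636). PORB was called higher with the block (0.00977), without the dimmest genes (0.0461), with a trended, robust variance (0.0493) and with just the arrays compared (0.0189). It was also called without DEX replicate 1 (0.0497), CHX replicate 1 (0.0493), DEX+CHX replicate 1 (0.045), DEX replicate 2 (0.0396) or DEX+CHX replicate 3 (0.0434).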

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

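The tests on rows that the annotation leaves unnamed were chosen after their values had been seen, bounds included, and so were the set of 6 genes used for the larger rises under CHX and the test on left-out arrays. The intervals in this section are bootstrap intervals of medians over genes or rows, which are not independent. They do not measure the spread between arrays.

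The difference between the 2 DEX effects marked 21 genes for a closer look. The largest positive differences on the log2 scale were those of SCRL26 (4.21), AT2G12462 (2.57), AT4G03420 (2.41), AT3G16660 (2.34) and AT2G25150 (1.88), and the largest negative ones those of AT1G07690 (-3.07), AT1G10640 (-2.46), AT2G19970 (-2.18), AT3G22060 (-2.16) and AT1G62770 (-2.11). When the DEX labels were shuffled within each CHX level, 6 of 100 relabellings, the real one included, called as many genes. By the rule set beforehand, this share was to be read as chance. The rule was judged unfit after the result, because a relabelling that keeps 1 real grouping carries its DEX effect into the difference. The count therefore cannot decide on chance for the 21, in either direction. The highest other was 283, from the relabelling that keeps both real groupings and turns the sign of 1, which adds the 2 DEX effects and so shows the structure that DEX gave the samples. The other 4 kept the real grouping of the arrays without CHX, and the 82 that kept neither grouping called at most 4.

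One candidate explanation for the smaller effects is that CHX alone had already raised these genes. Of the 14 genes, 4 (28.6%) had a CHX mean at or above their DEX mean, AT1G07690 among them, and the rest lay below it, such as AT1G10640, so the share leaves this open for the set. A low level that hides a rise without CHX could account for larger effects under CHX. Of the 6 genes with a positive difference that rose with DEX under CHX, 2 (33.3%) had a DEX mean in the range of the dimmest 30% of genes, which leaves that open too. A different response of the fusion's targets when protein synthesis is blocked, the factor of the design, stays open beside both.

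DEX alone lowered 68 genes, while 7 were lower with DEX under CHX, counts that came to 41 without DEX replicate 1, 41 without mock replicate 2, 44 without DEX replicate 2, 29 without mock replicate 3 and 32 without DEX replicate 3 for the 68, to 3 without DEX+CHX replicate 1, 3 without CHX replicate 2, 2 without DEX+CHX replicate 2 and 3 without DEX+CHX replicate 3 for the 7, and to 4 and 0 without replicate 3 of every treatment. The interaction tests the difference gene by gene, and among the 68 it was called for AT2G25150 alone, a call lost with any of 9 arrays left out. For the other genes a smaller fall under CHX was thus not shown individually. A low level under CHX that leaves no room to fall is argued against, since 10 of the 68 (14.7%) were in the dimmest range there. The same effect hidden by noise is argued against too: for 68 genes picked without 1 mock and 1 DEX array, the median change between the 2 left-out arrays was -0.311 to -0.626 over the 9 such pairs, while no DEX+CHX array differed from a CHX array by a median beyond -0.167. An effect of 0.5 times that size stays open, since the median under CHX (-0.077 over the 9) cleared that bar with its interval for 8 of the 9, not without mock replicate 1 and DEX replicate 2 (-0.0865, interval -0.16 to -0.038, against -0.155). That the falls need newly made protein may also fit the median of -0.0892 for the 68 (interval -0.165 to -0.0414), but a general disturbance by CHX predicts it too, so the 2 cannot be told apart.

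By the same left-out arrays, genes picked as the 184 were had a median rise of 0.716 to 0.864 without CHX and 0.311 to 0.326 with it. The 91 genes called higher with DEX under CHX had medians of 1.04 there and 0.669 without CHX. Part of that difference may come from picking genes on the arrays that show the larger value, which was not tested on left-out arrays for the 91.

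Rows outside the gene tests also carried signal. Of the 21686 rows without a single gene name, 152 were called for DEX against mock and 62 for DEX with CHX against CHX when all rows were tested. With CHX these rows shifted by a median of -0.551, and named rows by -0.0788. A single scaling factor per array is argued against by the difference of -0.472 (interval -0.494 to -0.454), and a dependence on level by the difference of -0.437 left after matching on the mock level (interval -0.71 to -0.236). Array medians of the rows without a single gene name were 6.21 to 6.30 without CHX and 5.30 to 5.41 with CHX. Those of the tested genes were 5.87 to 5.92 and 5.98 to 6.03. The matched difference was not read array by array. A block of 7083 rows with the lowest identifiers shifted by -1.51, and the other unnamed rows by -0.259, so that block may carry much of the fall but not clearly all of it. What these rows measure is not known here, and a wide effect of CHX on the RNA was not tested.

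For the counts of DEX against mock (252, highest other split 1), DEX with CHX against CHX (98, highest other 0) and CHX against mock (9088, highest other 0), 3 arrays against 3 make 10 splits, too few for a share under 0.05, and 1 of the 10 reached the real count each time. For the paired CHX arrays, the 3 other splits that part all 3 pairs and the 6 that part 1 gave 0. For the 48 genes called in both DEX comparisons, 1 of 100 relabellings reached the count and the highest other was 0, also among the 38 others that part all 3 pairs with CHX. This share argues against chance for the 2 groupings jointly, not for either alone, where the other splits are too few by themselves. It does not test the overlap itself, since the other splits of either comparison called at most 1 gene and left almost none to share.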

How the results depend on the processing

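Leaving out replicate 3 of all treatments was chosen after the data were seen. Testing all rows called 23040 rows for CHX against mock and 32 for the interaction. More rows were tested there, but for CHX the rows without a single gene name were also called more often. Of these 13946 of 21686 were called, against 9094 of 16722 named rows. A trended, robust variance gave 53 for the interaction. The cause of the 32 and of the 53 was not tested. With just the arrays compared, and so fewer arrays behind the spread, DEX against mock called 130 genes, DEX with CHX against CHX 61 and both 23. A fold minimum of 2 left 85, 51, 3833 for CHX and 20 in both, and an adjusted p of 0.01 left 120, 55 and 26 in both. Leaving out single arrays gave 150 (without mock replicate 3) to 229 genes for DEX against mock, 62 to 98 for DEX with CHX against CHX, 8416 to 9060 for CHX, 17 to 23 for the interaction and 31 to 43 in both. Leaving out replicate 3 throughout gave 62, 27, 8083, 2 and 14 with 8 arrays. The lateral root list ranged from 0.0192 to 0.421 under CHX with DEX and from 0.0451 to 0.475 for the interaction when single arrays were left out. With fry, which tests the list by itself and not against other genes, adjusted p was 0.0499 for the lateral root list with DEX under CHX, and for CHX 1.15e-05 for that list, 0.00315 for Aux/IAA, 8.35e-06 for GH3, 1.08e-05 for auxin synthesis and 1.08e-05 for expansins, where the cause was the question fry asks. The GH3 calls held in each left-out array (0.000648 to 0.0135 without CHX, 7.7e-07 to 0.000311 with CHX).

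With the replicate number as a block, 315 genes were called for DEX against mock, 105 for DEX with CHX against CHX, 9436 for CHX, 22 for the interaction and 52 in both. Mock and DEX arrays of the same number correlated at 0.0728, 0.0533 and 0.227, against at most 0.0506, 0.061 and -0.102 with other numbers. Mock and CHX arrays stood at 0.111, 0.077 and 0.211, against at most 0.0394, -0.00874 and -0.0993. So the numbers did not pair mock with DEX throughout. Same-numbered mock and CHX arrays did deviate together, more weakly than those of CHX and DEX with CHX. DEX arrays did so with DEX with CHX (0.0854, 0.0726 and 0.189, against at most 0.0222, 0.0365 and -0.0916). Mock arrays did so with DEX with CHX (0.199, 0.0445 and 0.222, against at most 0.0172, -0.0142 and -0.0607). DEX and CHX arrays did so for replicate 3 (0.173), not for replicates 1 and 2 (0.00615 and 0.0142). Shared deviations thus reached beyond the arrays with CHX, and the main tests did not model them. The block ended 5 named calls, those of AT5G06570, AT5G45650, AT3G54410, YUC11 and the interaction of AT2G25150, and added those of GH3.3 with DEX under CHX, EXPA7 with DEX and PORB with CHX. Of the 99 named calls, 13 were lost without some array. Over the named calls the settings with 1 array left out gave 1106 results on the same side and 82 weaker, leaving out replicate 3 throughout 69 and 30, and the others 732 and 34, and none of these calls was reversed. Signal over background was not available in the values used, so no level is called absent.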

Other observations

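The screen of gene families by symbol, and the tests on neighbouring genes, were chosen after the data had been seen. Among 37 families, the plant U-box ubiquitin ligases stood out under CHX. Of 10 measured PUB genes 8 rose and 1 fell, with a median log2 change of 2.52 (camera adjusted p = 7.49e-05, and 0.0597 with an estimated correlation). PUB54 rose by 4.85, PUB24 by 4.46, PUB26 by 2.78, PUB23 by 2.78 and PUB22 by 2.58, and PUB22, PUB23 and PUB24 are known as stress-induced ligases. The median kept its sign with quantile normalization (2.40) and with centring (2.41).

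Genes of the plastid genome were lower with CHX in 60 of 63 cases, with a median of -0.541 (camera adjusted p = 9.21e-09, but 0.522 with an estimated correlation, as these genes vary together). The median was -0.64 with quantile normalization and -0.659 with centring. With DEX none of the 63 was called. Under DEX without CHX, the family of UDP-glycosyltransferases ranked below other genes, with a median of -0.119 over 51 genes (camera adjusted p = 0.0162, and 0.136 with an estimated correlation). In it 3 genes fell, UGT73B1 by 0.86, UGT76C2, which glucosylates cytokinins, by 0.72 and UGT88A1 by 0.58, while UGT71B8 rose by 1.73 and UGT84A4 by 0.59. With quantile normalization 1 rose and 3 fell.

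Genes higher with DEX lay next to each other more than random sets did. In the gene order of TAIR10.1, 226 of the 228 genes called higher in either DEX comparison could be placed and held 12 adjacent pairs, such as AT3G57950 with AT3G57960, against a mean of 1.94 in 10000 random sets of measured genes (one-sided permutation p = 1e-04, the smallest they can give). Random placement is thus argued against. The pattern was not particular to DEX, since 226 genes with the largest rise under CHX held 24 such pairs. Tandem copies that share probe sequence may add to both counts, which was not tested.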
